A study of Homo sapiens with 12 samples.

How the data were processed

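Gene expression was measured on 12 Affymetrix arrays of 54675 probe sets. The arrays came from 2 human pancreatic cancer cell lines, FG and L3.6pl, each grown in hypoxia or in normoxia, with 3 arrays in each of the 4 groups. Per the labels' protocols, the cells were grown from frozen stock without passaging, typically for 9 days, in DMEM with serum. Hypoxic cultures spent the last 24 h at 1% oxygen balanced with nitrogen, and the other cultures were left untreated. Total RNA was isolated with Trizol and labelled with a biotin amplification kit, per the labels' protocols. The labels number the arrays of each group as replicates 1 to 3. Whether these came from separate cultures is not given in the sources used here.

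The deposited values are normalized intensities on a linear scale, which the authors made with RMA, per the submitters' processing notes. The notes give no RMA version and do not say how RMA's log2 output was turned back into linear intensities. The sorted log2 values of each array lay a median of 0.0138 and at most 0.145 from their mean over the arrays. Array medians ran from 39.1 to 41.4 intensity units, so no further normalization was applied. The log2 of each deposited intensity was taken here, and these values ran from 1.96 to 14.5. The number of arrays limits the precision of every value.

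Probe sets were named through the platform annotation's table of probe sets and genes, with symbols looked up by gene number in a gene table of assembly GRCh38.p14, from which no coordinates are printed. Leaving aside 62 control probe sets, 41091 probe sets had exactly 1 gene, 1801 had several genes and 11721 had no gene in that table. No gene was named from a probe set with several genes. For the 10523 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 19775 genes. Members of gene families with similar sequences, such as AKR1C, MAGEA and the HSP70 genes, can hybridise to each other's probes, and their values are uncertain for that reason.

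All 12 arrays entered 1 linear model with a mean for each group, fitted with limma 3.58.1 in R 4.3.3 and moderated with eBayes (8 residual degrees of freedom, 2.72 prior degrees of freedom). The 5 comparisons were hypoxia against normoxia in FG, the same in L3.6pl, L3.6pl against FG in normoxia, the same in hypoxia, and the interaction, which is the hypoxia effect in L3.6pl minus that in FG. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Errors of log2 fold changes are limma's standard errors. An exact test of 3 arrays against 3 cannot give a two-sided p below 0.1.

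The model, the rule for naming genes, 24 gene lists and most alternative settings were fixed before the data were examined. The lists cover targets of the hypoxia-inducible factors, oxygen sensing, glycolysis, mitochondrial respiration, sterol synthesis, matrix, angiogenic factors and cytokines, proliferation, DNA repair, the unfolded protein and integrated stress responses, heat shock proteins, immediate early genes, p53 targets, epithelial and mesenchymal markers, proteases, adhesion, growth factor receptors and ligands, NRF2 targets and xenobiotic metabolism, interferon-stimulated genes, classical and basal-like pancreatic tumour subtypes, acinar and endocrine pancreas, and stromal and blood cells. The last 2 of these hold markers of cell types that a pure culture should lack. Members were matched by current symbol, and through an older symbol only where the listed name is no current symbol. Some lists share members, such as 7 genes of the hypoxia targets and glycolysis and 5 of the hypoxia targets and the matrix list. Each list was tested with camera at its preset inter-gene correlation of 0.01, with adjustment over the 24 lists of a comparison. Camera with an estimated correlation and fry were alternatives, and list calls without an array use the preset correlation unless the text says otherwise. The count of members that pass when adjusted over the list alone is given beside the count over all genes.

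Named genes are the 8 with the largest log2 fold change in each direction whose calls came with no overlap between the 2 groups' arrays, and the 6 largest in each direction for the interaction. From each list, up to 4 members that passed with the smallest adjusted p and up to 2 that did not pass with the highest mean were added. A further 14 genes were always named, of which 13 were measured: CA9 had no probe set of its own among those used. Open reading frame, LOC and LINC style names and XIST were passed over. Genes outside this rule are said to be chosen after their values were seen.

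The alternative settings were a cyclic loess normalization, centring of each array on its median, a filter on dim genes, the mean of all probe sets of a gene, all probe sets tested singly, an intensity trend with robust moderation, array quality weights, a least absolute log2 fold change of 1, an adjusted p below 0.01, a fit of only the 6 arrays compared, the replicate number as a block, and leaving out each array in turn. A pairing of same-numbered arrays was tested through the correlation of their deviations from the group means, with pairing taken to hold where every correlation exceeded 0.1. The lines' arrays paired within each oxygen state, with correlations of 0.735, 0.528 and 0.675 in normoxia and 0.358, 0.444 and 0.462 in hypoxia for replicates 1 to 3. The labels do not say what the numbers mark, so this pairing comes from the data. A fit with same-numbered arrays of both lines as a block within each oxygen state (4 residual degrees of freedom) was therefore added after the data were seen. The same holds for that fit with the normoxia pair 1 or the hypoxia pair 3 left out, for a random block of those pairs, for a fit without 3 arrays that stand apart, for an estimated correlation in that fit and without FG normoxia replicate 1, and for 8 further gene lists.

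The fit was tested on simulated data with 19775 genes, in which 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. In the FG hypoxia comparison 29.9%, 74.6% and 95.5% of these were recovered, and in the L3.6pl hypoxia comparison 43.3%, 65.7% and 92.4%. The line comparison recovered 35.8%, 68.7% and 95.5% in normoxia and 40.3%, 61.2% and 93.9% in hypoxia. For the interaction the shares were 7.46%, 38.8% and 77.3%, and 10.4%, 47.8% and 86.4% with the block. Wrong calls were 9 of 142, 7 of 141, 0 of 133 and 0 of 130 in these 4 comparisons, and 0 of 82 and 4 of 100 in the interaction without and with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.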

Results

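Transcript levels of 19775 genes were measured in FG and L3.6pl, human pancreatic cancer lines that, per the series title, differ in metastatic potential. L3.6pl is known as a line selected in mice for metastasis. Each line was grown in normoxia or with its last 24 h at 1% oxygen, with 3 arrays per group and 12 in all. Arrays of the same group correlated with each other at a Pearson's r across genes of 0.974 to 0.996, where genes are not independent replicates. The first principal component, with 43.0% of the variance, had FG arrays from -45.97 to -30.8 and L3.6pl arrays from 33.6 to 44.2. On the second, with 27.6%, all hypoxia arrays were positive and all normoxia arrays negative. Changes below are log2 fold changes ± standard error from the limma model with 3 arrays in each group, and adjusted p values come from that model over all genes or from camera over the 24 gene lists.

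The first comparison asked which transcripts changed in FG cells in hypoxia. HSPA6, which encodes a stress-induced chaperone of the HSP70 family, rose 37.7-fold, from a log2 intensity of 5.04 ± 0.505 in normoxia to 10.28 ± 0.302 in hypoxia (SD, n = 3 arrays each). FOS, a subunit of the AP-1 transcription factor, rose 35.6-fold (5.16 ± 0.451, adjusted p = 0.000154). GDF15, a stress-induced cytokine, rose 33.7-fold (5.08 ± 0.849, adjusted p = 0.00408), and ADM, the vasodilator peptide adrenomedullin, rose 24-fold (4.59 ± 0.364, adjusted p = 0.000104). Without FG normoxia replicate 1, which stands apart, the GDF15 rise was 59.2-fold. CXCL8, the neutrophil chemokine interleukin 8, rose 20.8-fold. SOX2, a transcription factor of stem cells, fell by 2.78 ± 0.406 on the log2 scale (adjusted p = 0.00209). The largest rises also included AKAP12, a scaffold of protein kinase A, at 4.84 ± 0.443, TCIM at 4.43 ± 0.621, and ANKRD37 at 4.19 ± 0.390, although only 1 of the 2 ANKRD37 probe sets was positive. Among the largest falls were TMEM170B at -2.48 ± 0.215, the mitochondrial aspartate carrier SLC25A13 at -2.44 ± 0.359 (negative in 2 of its 3 probe sets) and PIGW at -2.42 ± 0.398. ARID5B and the guanine nucleotide exchange factor VAV3 followed at -2.34 ± 0.461 and -2.28 ± 0.460. ZNF367 at -2.89 was no longer called without FG hypoxia replicate 2 (adjusted p = 0.0519) and was at -3.63 without FG normoxia replicate 1. Without FG normoxia replicate 3, AKAP12 was at 5.43 and TCIM at 5.1.

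Textbook targets of the hypoxia-inducible factors rose together in FG. Of the 30 measured, 25 rose and 5 did not pass, and 29 were called when adjusted over the list alone. Their mean log2 change was 1.93 (camera, adjusted p = 2.73e-33; adjusted p = 0.0251 with an estimated correlation). With FG normoxia replicate 1 also left out, no list passed with an estimated correlation in any comparison, hypoxia targets being at 0.0509 in FG and 0.0601 in L3.6pl. ADM, ERO1A, an oxidase of the endoplasmic reticulum (2.77 ± 0.243), the glucose transporter SLC2A1 (1.87 ± 0.120) and ANGPTL4, a lipase inhibitor (1.55 ± 0.123), had the smallest adjusted p values. NDRG1, also a member of the list, rose by 2.96 ± 0.386. VEGFA, the main angiogenic growth factor, was at 1.09 ± 0.474 (adjusted p = 0.195) and did not pass. It was called, at 1.61, without FG normoxia replicate 1 (0.0309) and (0.00182) in a fit without the 3 arrays that stand apart (FG and L3.6pl normoxia replicate 1 and L3.6pl hypoxia replicate 3), chosen after the data were seen. Of 10 oxygen-sensing genes only the prolyl hydroxylase EGLN3 was called, at 2.38 ± 0.278, and 2 were called when adjusted over the list alone (list mean 0.358, adjusted p = 0.0956). HIF1A was at -0.11 ± 0.142 and EPAS1 at 0.49 ± 0.384, and neither passed.

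Glycolysis genes rose in 13 of 21 cases, with 17 called when adjusted over the list alone (list mean 1.28, adjusted p = 2.76e-16; adjusted p = 0.0251 with an estimated correlation). Examples were PFKFB3, which makes an activator of phosphofructokinase, at 3.46 ± 0.391, the enolase ENO2 at 3.18 ± 0.357 and the isomerase GPI at 1.10 ± 0.102. The matrix list had 11 of 16 members higher and 13 when adjusted over the list alone (mean 1.31, adjusted p = 5.57e-14; adjusted p = 0.0251 with an estimated correlation). Among them were the basement membrane collagens COL4A1 and COL4A2, at 1.53 ± 0.241 and 1.12 ± 0.150, tenascin (TNC) at 1.87 ± 0.231 and the collagen prolyl hydroxylase P4HA2 at 2.02 ± 0.192. Immediate early genes, which are also moved by handling, rose in 7 of 12 cases and in 9 when adjusted over the list alone (mean 1.84, adjusted p = 1.32e-12; adjusted p = 0.0251 with an estimated correlation). These included FOS, the phosphatase DUSP1 at 2.86 ± 0.282, ATF3 at 2.47 ± 0.143 and JUNB at 2.10 ± 0.175. Of 19 angiogenic factors and cytokines, 6 rose and 1 fell, with 11 called when adjusted over the list alone (mean 1, adjusted p = 3.34e-07; adjusted p = 0.0251 with an estimated correlation). CXCL8, the vasoconstrictor endothelin 1 (EDN1) at 2.93 ± 0.461 (3.54 without FG normoxia replicate 3) and PDGFB at 1.08 ± 0.152 rose, and FGF2 was at 0.40 ± 0.131 (adjusted p = 0.0822).

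Further FG lists passed with the preset correlation and were lost with an estimated one. Proteases and plasminogen genes had 3 of 18 members higher, and 4 when adjusted over the list alone (mean 0.641, adjusted p = 0.000288; adjusted p = 0.277 with an estimated correlation). The urokinase receptor PLAUR rose by 3.63 ± 0.306 and the gelatinase MMP9 by 0.93 ± 0.166. Mesenchymal markers rose in 6 of 19 cases, 7 when adjusted over the list alone (mean 0.558, adjusted p = 0.00209; adjusted p = 0.318 with an estimated correlation), with fibronectin (FN1) at 1.61 ± 0.310 and AXL at 1.45 ± 0.307 (not called without FG normoxia replicate 2, 0.0535), while VIM was at 0.30 ± 0.246 and did not pass. Stress-response genes rose in 6 of 20 cases, also 6 when adjusted over the list alone (mean 0.466, adjusted p = 0.00268; adjusted p = 0.517 with an estimated correlation), among them VLDLR at 1.84 ± 0.326 and PPP1R15A at 2.24 ± 0.436. That call ended without FG normoxia replicate 2 (adjusted p = 0.0553), and the list mean was 9.66 in FG normoxia replicate 1 against 8.74 in replicates 2 and 3. Without replicate 1 the mean change was 0.772. Basal-like subtype genes had 2 of 19 higher and 1 lower, 4 when adjusted over the list alone (mean 0.271, adjusted p = 0.0198; adjusted p = 0.393 with an estimated correlation), with SCEL at 1.53 ± 0.175. Without FG hypoxia replicate 3 its adjusted p was 0.0752. Epithelial genes had 2 of 21 higher, also 2 when adjusted over the list alone (mean 0.235, adjusted p = 0.0413; adjusted p = 0.318 with an estimated correlation), with the tight junction gene CLDN3 at 1.02 ± 0.161. CDH1 was at 0.55 ± 0.313 and did not pass. The epithelial call ended without FG normoxia replicate 2 (adjusted p = 0.0974), hypoxia replicate 1 (0.0702) or hypoxia replicate 2 (0.14).

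Heat shock genes rose in 2 of 8 cases in FG, also 2 when adjusted over the list alone, with DNAJB1, a cochaperone of HSP70, at 3.34 ± 0.647 and HSPB1 at 0.89 ± 0.159 (list mean 0.587, adjusted p = 0.0413; adjusted p = 0.436 with an estimated correlation). This call ended without FG normoxia replicate 1 (adjusted p = 0.248), hypoxia replicate 1 (0.142) or hypoxia replicate 2 (0.0818), without the 3 arrays that stand apart (0.113) and after cyclic loess (0.0565). Sterol synthesis genes fell in 3 of 14 cases and in 6 when adjusted over the list alone (mean -0.977, adjusted p = 7.05e-05; adjusted p = 0.393 with an estimated correlation). FDPS, the farnesyl diphosphate synthase, fell by 1.30 ± 0.259, and the list mean was 10.34 in FG normoxia replicate 1 against 9.41 in replicates 2 and 3. Of 8 DNA repair genes 2 fell, also 2 when adjusted over the list alone (mean -0.597, adjusted p = 0.0485; adjusted p = 0.517 with an estimated correlation). Their call ended without any of 7 single arrays (adjusted p from 0.0507 to 0.218), with the filter on dim genes (0.101) and with the mean of all probe sets (0.0854).

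Proliferation genes did not pass in FG, with 0 of 26 called and a list mean of -0.262 (adjusted p = 0.425). Their mean level was 8.20 in FG normoxia replicate 1 and 10.1 in replicates 2 and 3, and without replicate 1 the list mean was -0.89 (adjusted p = 8.36e-07; adjusted p = 0.343 with an estimated correlation). Without normoxia replicate 2 or 3 it was 0.0448 or 0.0633, and without hypoxia replicate 1, 2 or 3 -0.454, -0.123 or -0.209, none of them called. MKI67, a marker of cycling cells, was at 0.53 ± 0.523, and at -0.232 without normoxia replicate 1. Mitochondrial respiration had 2 of 19 members lower and 3 when adjusted over the list alone (mean -0.147, adjusted p = 0.131), and without FG normoxia replicate 1 it passed (adjusted p = 0.0147). So did adhesion (adjusted p = 0.0199), growth factor receptors (0.0093) and oxygen sensing (0.0373), none of them with an estimated correlation. With all arrays, adhesion had 2 of 18 higher and 1 lower (mean 0.108, adjusted p = 0.241), including the integrin ITGA2 at 1.29 ± 0.231. Growth factor receptors and ligands had 2 of 15 higher and 2 lower, and 6 when adjusted over the list alone (mean 0.314, adjusted p = 0.149). The EGFR ligands EREG and TGFA rose by 2.19 ± 0.279 and 1.29 ± 0.2, the receptor ERBB3 fell by 1.05 ± 0.151, and EGFR was at 0.81 ± 0.401 (adjusted p = 0.258). Interferon-stimulated genes had 2 of 18 higher and 2 lower (mean -0.134, adjusted p = 0.257), with IFIT3 at -1.26 ± 0.181 and OAS1 at -0.75 ± 0.146. NRF2 targets and xenobiotic metabolism had 2 of 21 higher and 1 lower (mean 0.172, adjusted p = 0.149), with ALDH1A3 at 1.44 ± 0.225. The p53 targets had 2 of 16 higher and 1 lower. Their mean was 0.202, their median -0.118 and the camera direction negative (adjusted p = 0.884). Classical subtype genes had 2 of 18 higher (mean 0.128, adjusted p = 0.241), TFF1 at 2.20 ± 0.272 and GATA6 at 1.90 ± 0.193. Stromal and blood markers had 0 of 11 called (mean 0.167, adjusted p = 0.131). Acinar and endocrine genes had 0 of 11 called, with a mean of -0.0428, a median of 0.0286 and a positive camera direction (adjusted p = 0.666).

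In all, 2117 genes were called in FG, 838 higher and 1279 lower in hypoxia, of which 411 and 439 changed at least 2-fold. The 3 values of one group all lay above the 3 of the other in 2111 of them, and in 27.9% of all genes where chance gives 10%. The count was 1325 without FG normoxia replicate 2 and 1029 without FG hypoxia replicate 2.

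In L3.6pl, hypoxia raised ACKR3, a scavenger receptor for the chemokine CXCL12, 78.3-fold, from a log2 intensity of 3.56 ± 0.865 to 9.85 ± 0.511 (SD, n = 3 arrays each), although 1 of its 3 probe sets was not positive. HAS3, a hyaluronan synthase, rose 17.5-fold (4.13 ± 0.3, adjusted p = 9.2e-05) and CXCR4, the signalling receptor for CXCL12, rose 11.4-fold (3.51 ± 0.392, adjusted p = 0.000885). COXFA4L2 (formerly NDUFA4L2), which lowers respiratory activity in hypoxia, rose 14.5-fold, NDRG1 13.7-fold, ADM 13.2-fold and EGLN3 10.8-fold. PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, fell by 2.31 ± 0.369 (adjusted p = 0.00485), and ACAT2, an early enzyme of sterol synthesis, by 2.02 ± 0.289. BRI3BP followed at -2.14 ± 0.274. HSPA6 was 15-fold higher (3.91 ± 1.05, adjusted p = 0.0499), but its log2 intensities in hypoxia were 9.91, 10.6 and 5.26 in replicates 1 to 3, and leaving out any array other than FG normoxia replicate 1 or L3.6pl hypoxia replicate 3 ended its call (adjusted p from 0.0658 to 0.183). Without L3.6pl hypoxia replicate 1, 2 or 3 its rise was 9.47-fold, 7.55-fold or 47.4-fold. The monocarboxylate carrier family member SLC16A14 at -2.08 lost its call without any of 4 single arrays (adjusted p from 0.0659 to 0.0902).

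Hypoxia targets rose in L3.6pl in 22 of 30 cases, and in 28 when adjusted over the list alone, with a mean log2 change of 1.96 (adjusted p = 8.21e-36; adjusted p = 0.0461 with an estimated correlation). Besides ADM and EGLN3 these included P4HA2 at 2.70 ± 0.192, ANGPTL4 at 1.77 ± 0.123 and SLC2A1 at 1.39 ± 0.120. LDHA at 0.63 ± 0.199 (adjusted p = 0.0903), PGK1 at 0.76 ± 0.206 (adjusted p = 0.0536) and VEGFA at 0.57 ± 0.474 (adjusted p = 0.576) did not pass. Without the 3 arrays that stand apart VEGFA was called at 1.23 (adjusted p = 0.00911). Glycolysis genes rose in 13 of 21 cases, 15 when adjusted over the list alone (mean 1.15, adjusted p = 6.33e-17; adjusted p = 0.0489 with an estimated correlation), with PFKFB4 at 2.37 ± 0.248 and GPI at 1.23 ± 0.102. Oxygen-sensing genes had 2 of 10 higher and 5 when adjusted over the list alone (mean 0.508, adjusted p = 0.0379; adjusted p = 0.148 with an estimated correlation). That call ended without L3.6pl normoxia replicate 3 (adjusted p = 0.0924), hypoxia replicate 1 (0.0842) or hypoxia replicate 2 (0.108). HIF1A was at -0.47 ± 0.142 (adjusted p = 0.0775) and EPAS1 at 0.53 ± 0.384 (adjusted p = 0.501). Without FG normoxia replicate 1, LDHA (0.00119), PGK1 (0.00145) and HIF1A (0.0373) were called.

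Matrix genes rose in 8 of 16 cases in L3.6pl, 9 when adjusted over the list alone (mean 1.19, adjusted p = 9.83e-11; adjusted p = 0.0597 with an estimated correlation), with the lysyl oxidase LOXL2 at 2.85 ± 0.330 and the collagen hydroxylases P4HA1 at 1.76 ± 0.221 and PLOD1 at 1.40 ± 0.172. Immediate early genes rose in 7 of 12 cases, also 7 when adjusted over the list alone (mean 1.11, adjusted p = 1.19e-08; adjusted p = 0.0597 with an estimated correlation), with JUN at 2.51 ± 0.276 and DUSP1 at 1.82 ± 0.282. Angiogenic factors and cytokines had 5 of 19 higher and 1 lower, 7 when adjusted over the list alone (mean 0.726, adjusted p = 1.58e-05; adjusted p = 0.0597 with an estimated correlation). CXCL8 rose by 2.78 ± 0.490 and angiogenin (ANG) by 1.96 ± 0.242. FGF2 fell by 0.52 ± 0.131 (adjusted p = 0.0411), a call that ended when any of 8 single arrays was left out (adjusted p from 0.05 to 0.164). Proteases and plasminogen genes rose in 5 of 18 cases, 6 when adjusted over the list alone (mean 0.758, adjusted p = 4.74e-06; adjusted p = 0.132 with an estimated correlation), with PLAUR at 2.53 ± 0.306, its ligand urokinase (PLAU) at 2.22 ± 0.278 and the protease inhibitor TIMP3 at 0.94 ± 0.162. MMP9 was at 0.25 ± 0.166 (adjusted p = 0.442).

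Both mesenchymal and epithelial lists were higher in hypoxic L3.6pl. Mesenchymal markers rose in 4 of 19 cases, 6 when adjusted over the list alone (mean 0.589, adjusted p = 3.58e-05; adjusted p = 0.155 with an estimated correlation), with the receptor kinase AXL at 2.43 ± 0.307 and integrin ITGA5 at 1.81 ± 0.159, and VIM at 0.33 ± 0.246 did not pass. Epithelial genes rose in 4 of 21 cases, also 4 when adjusted over the list alone (mean 0.366, adjusted p = 0.00101; adjusted p = 0.132 with an estimated correlation), with the transcription factor ELF3 at 1.29 ± 0.225 and the plakophilin PKP3 at 0.53 ± 0.0940. CDH1, the epithelial cadherin, rose by 1.26 ± 0.313 (adjusted p = 0.0375), a call that ended without any of 5 single arrays (0.0529 to 0.149). Adhesion genes rose in 6 of 18 cases, 7 when adjusted over the list alone (mean 0.505, adjusted p = 0.000424; adjusted p = 0.159 with an estimated correlation), including ITGA5 and ITGA2 (1.34 ± 0.231). Basal-like genes had 4 of 19 higher and 1 lower, 8 when adjusted over the list alone (mean 0.535, adjusted p = 5.77e-05; adjusted p = 0.148 with an estimated correlation), with SCEL at 1.66 ± 0.175. Their mean level was 8.89 in hypoxia replicate 3 against 8.38 in replicates 1 and 2, and without the 3 arrays that stand apart the mean change was 0.310 (0.00723). Growth factor receptors and ligands had 4 of 15 higher and 1 lower, 6 when adjusted over the list alone (mean 0.506, adjusted p = 0.00447; adjusted p = 0.195 with an estimated correlation). EREG and TGFA rose by 2.06 ± 0.279 and 1.71 ± 0.2, and EGFR was at 0.89 ± 0.401 (adjusted p = 0.232). The interaction of this list did not pass (mean 0.192, adjusted p = 0.187), nor did that of oxygen sensing (mean 0.150, adjusted p = 0.518). Stress-response genes rose in 2 of 20 cases, also 2 when adjusted over the list alone (mean 0.315, adjusted p = 0.0124; adjusted p = 0.507 with an estimated correlation), with VLDLR at 2.06 ± 0.326. Their call ended without L3.6pl normoxia replicate 2 (adjusted p = 0.0735), normoxia replicate 3 (0.0822) or hypoxia replicate 2 (0.203), and the list mean was 9.40 in normoxia replicate 1 against 8.79 in replicates 2 and 3. Without that array the mean change was 0.519.

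Lists that were lower in hypoxic L3.6pl concerned sterols, the cell cycle, respiration and interferon. Sterol synthesis genes fell in 3 of 14 cases and in 9 when adjusted over the list alone (mean -1.18, adjusted p = 1.15e-06; adjusted p = 0.195 with an estimated correlation), with FDPS at -1.42 ± 0.259. The squalene epoxidase SQLE was at -2.13 ± 0.452, a call that ended without L3.6pl hypoxia replicate 1 (adjusted p = 0.0676) or 2 (0.0843). The sterol list mean was 9.68 in L3.6pl normoxia replicate 1 against 8.65 in replicates 2 and 3, and 8.19 in hypoxia replicate 3 against 7.62 in replicates 1 and 2. Proliferation genes fell in 2 of 26 cases, 3 when adjusted over the list alone (mean -0.937, adjusted p = 9.16e-06; adjusted p = 0.388 with an estimated correlation). These were the replication licensing factors MCM2 at -1.55 ± 0.410 and MCM3 at -1.65 ± 0.402. The MCM2 call ended without any of 8 single arrays (adjusted p from 0.0565 to 0.185) and the MCM3 call without any of 6 (0.0555 to 0.133). Mean proliferation levels were 9.39 in L3.6pl normoxia replicate 1 against 10.22 in replicates 2 and 3, and 9.24 in hypoxia replicate 3 against 8.88 in replicates 1 and 2. MKI67 was at -0.56 ± 0.523 and did not pass. Mitochondrial respiration genes fell in 5 of 19 cases, 8 when adjusted over the list alone (mean -0.373, adjusted p = 1.75e-05; adjusted p = 0.195 with an estimated correlation), with citrate synthase (CS) at -0.67 ± 0.158 and the ATP synthase subunit ATP5F1B at -0.51 ± 0.117, calls that ended without any of 5 (adjusted p from 0.0542 to 0.119) and 4 (0.0514 to 0.119) single arrays. DNA repair genes fell in 2 of 8 cases, 6 when adjusted over the list alone (mean -0.960, adjusted p = 0.000227; adjusted p = 0.195 with an estimated correlation). BRCA1 was at -1.70 ± 0.317, a call that ended without L3.6pl normoxia replicate 2 (adjusted p = 0.056) or hypoxia replicate 2 (0.0522). Interferon-stimulated genes fell in 3 of 18 cases, 7 when adjusted over the list alone (mean -0.448, adjusted p = 0.000424; adjusted p = 0.195 with an estimated correlation), with IFIT3 at -1.47 ± 0.181.

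Other lists did not pass in L3.6pl. Heat shock genes had 0 of 8 called, with a mean of 0.00525, a median of -0.0875 and a negative camera direction (adjusted p = 0.584), and p53 targets had 0 of 16 called (mean 0.150, adjusted p = 0.463). GDF15 among them was at 2.73 ± 0.849, and was called without L3.6pl hypoxia replicate 3 (3.65, adjusted p = 0.0112) or FG normoxia replicate 1 (0.0399). NRF2 targets had 2 of 21 higher, with a mean of -0.064, a median of -0.0272 and a positive camera direction (adjusted p = 0.662). Classical subtype genes had 3 of 18 higher, GATA6 at 1.39 ± 0.193 among them, with a mean of 0.155, a median of -0.0301 and a positive direction (adjusted p = 0.424). The bile salt lipase CEL, at 3.13 ± 0.270, was the 1 of 11 acinar and endocrine genes that rose (mean 0.212, median -0.00244, positive direction, adjusted p = 0.463). Of 11 stromal and blood markers (mean 0.318, adjusted p = 0.272) only LAPTM5 was called, at 1.31 ± 0.333, which ended without any of 7 single arrays (0.0538 to 0.132). In all, 1357 genes were called, 769 higher and 588 lower, of which 341 and 196 changed at least 2-fold. The groups' values did not overlap in any of the 1357, nor in 24.4% of all genes where chance gives 10%. The count was 508 without L3.6pl normoxia replicate 2, 734 without normoxia replicate 3, 853 without hypoxia replicate 1, 569 without hypoxia replicate 2 and 2436 without hypoxia replicate 3.

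**Figure D1:**
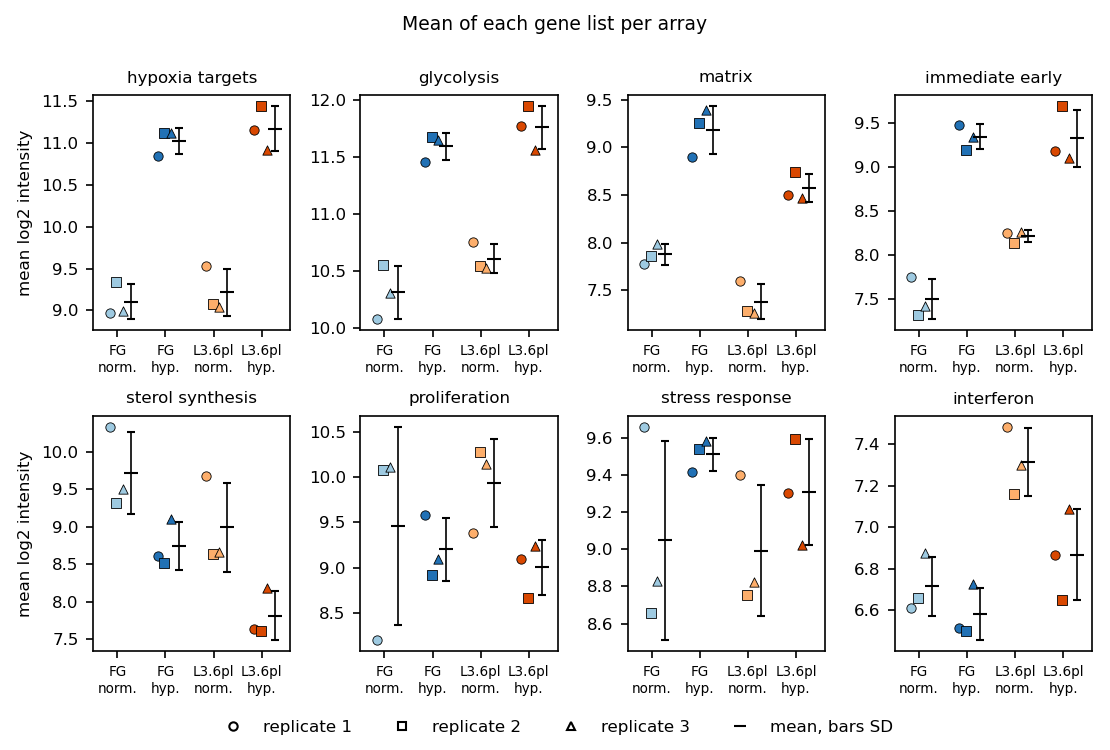
Mean log2 intensity of 8 gene lists on each array (points, shaped by replicate), with the mean and SD of each group of 3 arrays (bars). Hypoxia targets, glycolysis, matrix and immediate early genes are higher in every hypoxia array than in the normoxia arrays of its line, and FG normoxia replicate 1 lies at 8.20 for proliferation against a mean of 10.1 in replicates 2 and 3.

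The hypoxia effects in the lines were then compared. A core of genes moved the same way in both: 403 rose in both lines, among them ADM, NDRG1, EGLN3, SLC2A1, ANGPTL4, P4HA2, PLAUR, CXCL8 and GPI, and 354 fell in both, among them FDPS and IFIT3. Independent calls would have given 32.6 and 38 shared genes, and 2 genes were called in opposite directions. Of the 2715 genes called in either line, 93.6% had the same sign in both. Across all genes, which are not independent replicates, the effects correlated at a Pearson's r of 0.705 and a Spearman's rho of 0.593. Their covariance was 0.147, of which 0.0257 came from deviations shared by same-numbered arrays. The overlap of 757 was 503 without FG normoxia replicate 2, 453 without FG hypoxia replicate 2, 337, 462, 460 and 386 without L3.6pl normoxia replicate 2, normoxia replicate 3, hypoxia replicate 1 and hypoxia replicate 2, and 1537 without L3.6pl hypoxia replicate 3.

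**Figure D2:**
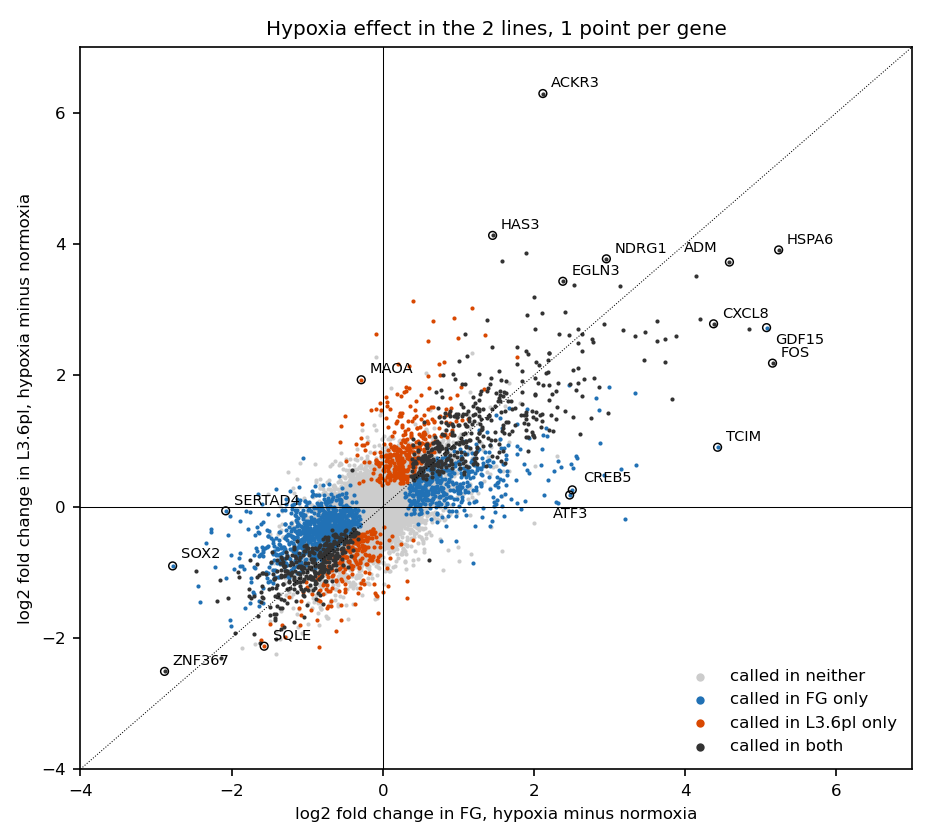
Log2 fold change in hypoxia of each gene (points) in FG (x axis) and in L3.6pl (y axis), coloured by the lines in which it was called, with the dotted line marking equal effects; XIST and Y-linked genes are left out. Most genes called in both lines lie near the dotted line, while ACKR3 and HAS3 lie above it and ATF3, CREB5 and TCIM below it.

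The interaction asked which of these responses differed between the lines. ATF3, a transcription factor of the integrated stress response, rose in FG by 2.47 ± 0.143 and was at 0.18 in L3.6pl (adjusted p = 0.563), an interaction of -2.30 ± 0.202 (adjusted p = 0.00259). CREB5, another transcription factor of the same superfamily, rose by 2.51 in FG and was at 0.25 in L3.6pl (interaction -2.25 ± 0.186, adjusted p = 0.00259). Both calls held when any array was left out and ended with the mean of all probe sets (adjusted p = 0.0754 for ATF3 and 0.057 for CREB5). MAOA, the monoamine oxidase A, rose by 1.93 in L3.6pl and was at -0.29 in FG (interaction 2.22 ± 0.276, adjusted p = 0.0289). SERTAD4 fell by 2.08 in FG, from 7.33 to 5.25, and was low in L3.6pl in both states at 4.95 and 4.88 (interaction 2.01 ± 0.227, adjusted p = 0.0193). RAB31, a regulator of vesicle traffic, rose by 1.27 in L3.6pl and was at 0.17 in FG (interaction 1.10 ± 0.134, adjusted p = 0.0289). The calls of MAOA, SERTAD4 and RAB31 ended without any of 8 (adjusted p from 0.054 to 0.114), 5 (0.0544 to 0.0886) and 7 (0.061 to 0.122) single arrays. Other settings ended the SERTAD4 call (mean of all probe sets, 0.0974) and the RAB31 call (trend and robust moderation, 0.0548).

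These were the 5 interaction calls, 3 higher and 2 lower in L3.6pl, beside 1427 genes at an unadjusted p below 0.05. For the other genes named above, a call in 1 line only was not shown by this fit to be a difference between the lines. With same-numbered arrays of the lines as a block within each oxygen state, 703 genes were called, 503 higher and 200 lower, including all 5. Leaving out the pair of normoxia replicates 1, which stand apart, gave 271 calls, 233 of them among the 703, and leaving out the hypoxia pair 3 instead gave 1239, 651 of them among the 703. Of 170 genes named in a hypoxia comparison, 1 was called without the block, 30 with it, and of these 19 without the normoxia pair, 28 without the hypoxia pair and 18 in both such fits. Among the largest, chosen after their values were seen, were ACKR3 at 4.17 (adjusted p = 0.00964 with this block and 0.0508 without), TCIM at -3.53 (0.0601 without the normoxia pair), CGA at -3.39, FOS at -2.97, the matricellular gene CCN1 at -2.71, HAS3 at 2.68 and the BMP target ID3 at -2.57. The block also brought calls for CEL at 2.73 (adjusted p = 0.00403 and a standard error of 0.201 with it, 0.0532 and 0.382 without), the ubiquitin-like ISG15 at -2.05 (0.0123), GDF15 at -2.35 (0.0346; -1.87 without the hypoxia pair, and -1.43 unblocked without L3.6pl hypoxia replicate 3, not called), CXCL8 at -1.59 (0.0289), FGF2 at -0.92 (0.0269) and CDH1 at 0.71 (0.0376), of which CXCL8 (0.069) and CDH1 (0.0977) were not called without the normoxia pair. The smaller falls of SOX2, VAV3, ARID5B and TMEM170B in L3.6pl gave 1.88 (0.0125), 1.94 (0.00713), 1.78 (0.00713) and 1.49 (0.00757). TNC was at -1.79 (0.0312), LOXL2 at 1.47 (0.0386) and ITGA5 at 1.46 (0.0229), the last 2 not called without the normoxia pair (0.0918 and 0.0628). The unblocked count was 3 without FG normoxia replicate 2, 23 without FG normoxia replicate 3, 3 without FG hypoxia replicate 1, 2 without FG hypoxia replicate 2, 13 without FG hypoxia replicate 3, and 2 each without L3.6pl normoxia replicate 2 and normoxia replicate 3.

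Among lists, immediate early genes had a smaller effect in L3.6pl (mean interaction -0.733, adjusted p = 0.000973), with 1 of 12 members lower and 4 when adjusted over the list alone, and so did heat shock genes (mean -0.582, adjusted p = 0.00215, 0 of 8 called; -0.462, 0.00311, without the 3 arrays that stand apart, each low in them for its group). Proliferation genes had a mean interaction of -0.675 (adjusted p = 0.00038, 0 of 26 called), which was -0.043 without FG normoxia replicate 1 (adjusted p = 0.657) and -0.442 without the 3 arrays (0.000765). Mitochondrial respiration was at -0.226 (adjusted p = 0.00691, 0 of 19 called), and not called without FG normoxia replicate 1 (0.0954) or L3.6pl hypoxia replicate 2 (0.0837). Adhesion was at 0.397 (adjusted p = 0.0077, 0 of 18 called and 1 when adjusted over the list alone), lost without FG normoxia replicate 1 (0.117) or L3.6pl hypoxia replicate 2 (0.0511) and 0.244 without the 3 arrays (0.0353). Interferon-stimulated genes were at -0.315 (adjusted p = 0.0319, 0 of 18 called and 3 when adjusted over the list alone), lost without any of 5 single arrays (0.0632 to 0.266). All 6 lists had an adjusted p = 0.761 with an estimated correlation. The block brought DNA repair (mean -0.363, adjusted p = 0.0286, against 0.116 without it) and NRF2 targets (mean -0.236, adjusted p = 0.0121, against 0.289) past the threshold. Hypoxia targets had a mean interaction of 0.036, a median of -0.0766 and a negative camera direction (adjusted p = 0.872). Without the 3 arrays that stand apart the interferon call ended (0.0948), and hypoxia targets (0.391, 0.000247), oxygen sensing (0.279, 0.0373), epithelial genes (0.150, 0.0382) and NRF2 targets (-0.422, 0.00311) were called, but none of the 24 lists with an estimated correlation (lowest adjusted p = 0.615).

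**Figure D3:**
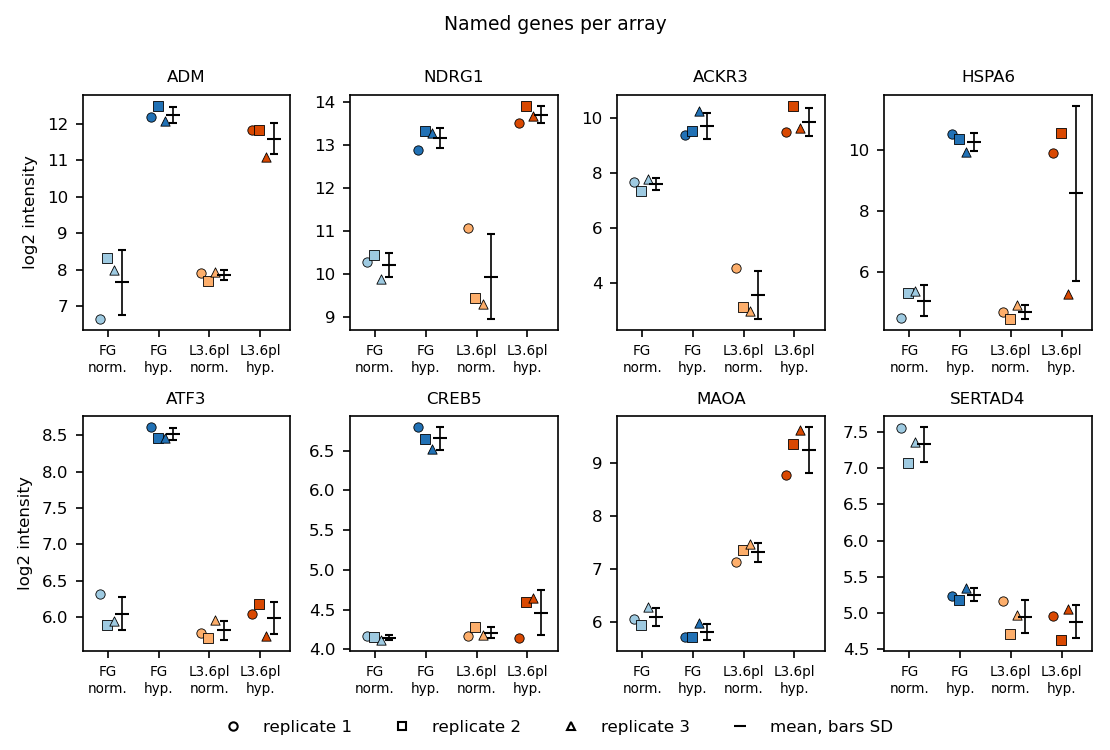
Log2 intensity of 8 named genes on each array (points, shaped by replicate), with the mean and SD of each group of 3 arrays (bars). ADM, NDRG1 and ACKR3 are higher in all hypoxia arrays of both lines, HSPA6 stays at 5.26 in L3.6pl hypoxia replicate 3, and ATF3 and CREB5 rise by 2.47 and 2.51 in FG against 0.18 and 0.25 in L3.6pl.

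The lines were compared in normoxia to ask how cells of different metastatic potential differ at baseline. With 1 line of each potential, no difference between the lines can be ascribed to it. SOSTDC1, a secreted antagonist of BMP and WNT signalling, was 101-fold higher in L3.6pl than in FG, at a log2 intensity of 10.83 ± 0.412 against 4.17 ± 0.0944 (SD, n = 3 arrays each). The neurotrophin receptor NTRK2 was 90.3-fold higher (6.5 ± 0.254, adjusted p = 2.05e-07), the squamous keratin KRT13 62.7-fold (36-fold without FG normoxia replicate 1, which stands apart) and the interleukin 1 receptor IL1R1 36.5-fold. BCHE, the plasminogen activator PLAT, ANXA10 and the receptor phosphatase PTPRZ1 were higher by 4.90 ± 0.343, 4.52 ± 0.519, 4.46 ± 0.454 and 4.44 ± 0.239. FG had higher levels of the cancer-testis gene MAGEA6 (-7.32 ± 0.163, adjusted p = 3.05e-09), of CPS1, the first enzyme of the urea cycle (-6.75 ± 0.268), of mesothelin, MSLN (-5.71 ± 0.443, and -5.02 without FG normoxia replicate 1), and of the surface antigen CD24 (-5.51 ± 0.230). STEAP4, the lectin-like receptor OLR1 and MAGEA12 were at -5.78 ± 0.176, -5.73 ± 0.181 and -5.57 ± 0.222. COL3A1, a fibrillar collagen, was at 11.02 in FG and 5.6 in L3.6pl.

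Growth factor receptors and ligands were higher in L3.6pl, with 7 of 15 members higher and 1 lower, and 9 called when adjusted over the list alone (mean 0.832, adjusted p = 0.00537; adjusted p = 0.481 with an estimated correlation). EREG at 2.46 ± 0.279, the IGF-binding protein IGFBP6 at 1.90 ± 0.266 and TGFA at 1.51 ± 0.2 were higher and the receptor MET was lower at -0.97 ± 0.168. EGFR was at 1.58 ± 0.401 (adjusted p = 0.0293), a call that ended without any of 4 single arrays (0.087 to 0.106). Interferon-stimulated genes were higher in 8 of 18 cases and lower in 1, with 12 called when adjusted over the list alone (mean 0.601, adjusted p = 0.000141; adjusted p = 0.481 with an estimated correlation). IFIT2 at 1.69 ± 0.309, IFIT3 at 1.03 ± 0.181 and OAS1 at 0.89 ± 0.146 were among them. Angiogenic factors and cytokines had 6 of 19 higher and 1 lower, 7 when adjusted over the list alone (mean 0.614, adjusted p = 0.0179; adjusted p = 0.481 with an estimated correlation), with the chemokine CCL20 at 3.35 ± 0.499 (3.98 without FG normoxia replicate 3) and the lymphangiogenic factor VEGFC at 2.93 ± 0.243. CXCL8 was at 2.10 ± 0.490, not called without any of 4 single arrays (adjusted p from 0.0558 to 0.0835). Basal-like genes had 6 of 19 higher and 2 lower, 11 when adjusted over the list alone (mean 0.510, adjusted p = 0.0218; adjusted p = 0.538 with an estimated correlation), with FGFBP1 at 1.57 ± 0.234 and LY6D at -2.10 ± 0.279.

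Sterol synthesis was lower in L3.6pl in 2 of 14 cases, 3 when adjusted over the list alone (mean -0.726, adjusted p = 0.000791; adjusted p = 0.538 with an estimated correlation), with SC5D at -1.77 ± 0.332, and had a mean of -0.416 without FG normoxia replicate 1 (0.0372). Epithelial genes had 1 of 21 higher and 2 lower, 6 when adjusted over the list alone (mean -0.267, adjusted p = 0.0174; adjusted p = 0.481 with an estimated correlation), with ELF3 at -1.13 ± 0.225. CDH1 was at -0.64 ± 0.313 (adjusted p = 0.267, and 0.00238 with the block) and VIM at 0.79 ± 0.246 (0.0711, and 0.00805 with the block or 0.00623 without FG normoxia replicate 1). Glycolysis genes were higher in 4 of 21 cases, 7 when adjusted over the list alone (mean 0.295, adjusted p = 0.00652; adjusted p = 0.538 with an estimated correlation), with ALDOA at 0.54 ± 0.0849. This call ended without FG normoxia replicate 1 (adjusted p = 0.0819) and without the 3 arrays that stand apart (0.247). SLC2A1 was at 0.40 ± 0.120 (adjusted p = 0.0622, and 0.0142 with the block). Heat shock genes had 1 of 8 higher, BAG3 at 1.04 ± 0.130, and 2 when adjusted over the list alone (mean 0.414, adjusted p = 0.0216; adjusted p = 0.538 with an estimated correlation), and were not called without FG normoxia replicate 1 (0.150). Mitochondrial respiration had 1 of 19 higher, the dehydrogenase subunit OGDH at 0.85 ± 0.119, also 1 when adjusted over the list alone (mean 0.232, adjusted p = 0.0308; adjusted p = 0.650 with an estimated correlation). Its call ended without FG normoxia replicate 1 (0.219), L3.6pl normoxia replicate 2 (0.0823) or normoxia replicate 3 (0.118), with the filter (0.0692) and with the mean of probe sets (0.0685). Immediate early genes had 2 of 12 higher, EGR1 at 4.38 ± 0.735 (5.08 without FG normoxia replicate 1) and IER3 at 2.29 ± 0.282, and 4 when adjusted over the list alone (mean 0.718, adjusted p = 0.0348; adjusted p = 0.538 with an estimated correlation). That call ended with the block (0.0563), with the filter (0.0692) and without FG normoxia replicate 2 (0.0596), FG normoxia replicate 3 (0.0726), L3.6pl normoxia replicate 1 (0.0741) or L3.6pl hypoxia replicate 2 (0.061).

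Several lists fell short of the threshold in normoxia. Matrix genes had 1 of 16 higher and 2 lower, 4 when adjusted over the list alone (mean -0.495, adjusted p = 0.0502, and 0.0371 with the block), with TGFBI at -3.62 ± 0.388 and FN1 at -1.64 ± 0.310, and were called without FG normoxia replicate 1 (0.0372), L3.6pl normoxia replicate 1 (0.0096) or L3.6pl hypoxia replicate 3 (0.045). Proliferation had 0 of 26 called (mean 0.476, adjusted p = 0.0626, and 0.0112 with the block), and passed without FG normoxia replicate 2 (0.00151), FG normoxia replicate 3 (0.0048) or L3.6pl normoxia replicate 1 (0.00665) and after cyclic loess (0.0469). Without FG normoxia replicate 1 the mean was -0.156 (0.309), of the opposite sign, and without the 3 arrays that stand apart it was 0.122 (0.635). DNA repair had 0 of 8 called (mean 0.398, adjusted p = 0.118, and 0.0371 with the block). Mesenchymal markers had 2 of 19 higher and 5 lower (mean -0.365, adjusted p = 0.344), with TGFB1 at 1.57 ± 0.211 and TAGLN, an actin-binding protein, at -3.56 ± 0.646 (-4.49 without FG normoxia replicate 1 and -2.78 without replicate 3). Proteases had 5 of 18 higher and 3 lower, 11 when adjusted over the list alone (mean 0.360, adjusted p = 0.322), with the collagenase MMP1 at 2.97 ± 0.536 and the matrilysin MMP7 at -3.09 ± 0.344. NRF2 targets and xenobiotic metabolism had 3 of 21 higher and 3 lower, with a mean of 0.0211 and a negative camera direction (adjusted p = 0.986). The aldehyde dehydrogenases ALDH1A3 and ALDH1A1 were at 3.84 ± 0.225 and -3.30 ± 0.449. Adhesion had 2 of 18 higher and 1 lower (mean 0.189, adjusted p = 0.174), with L1CAM at -2.73 ± 0.279, and oxygen sensing had 3 of 10 higher and 1 lower (mean 0.326, adjusted p = 0.202), with HIF1A at 0.89 ± 0.142. Hypoxia targets had 2 of 30 higher and 1 lower (mean 0.113, adjusted p = 0.344), p53 targets 2 of 16 higher and 1 lower (mean 0.167, adjusted p = 0.555) and the classical subtype 3 of 18 higher and 1 lower (mean 0.303, adjusted p = 0.411). Stress response had 1 of 20 higher (mean -0.055, adjusted p = 0.908) and acinar and endocrine genes 1 of 11 higher (mean 0.161, adjusted p = 0.352). Stromal and blood markers had 1 of 11 higher and 1 lower, with a mean of -0.295, a median of 0.0467 and a negative direction (adjusted p = 0.970), COL3A1 being the lower one. In all, 2116 genes were called in normoxia, 1020 higher and 1096 lower in L3.6pl, of which 396 and 488 differed at least 2-fold. Values did not overlap between the lines in 2114 of them, nor in 28.1% of all genes where chance gives 10%. The count was 4576 with the block, 1383 without FG normoxia replicate 2, 1254 without L3.6pl normoxia replicate 2 and 1354 without L3.6pl normoxia replicate 3.

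In hypoxia, the line comparison asked the same of cells under the low oxygen that tumours meet. SOSTDC1 was 80.4-fold higher in L3.6pl (10.07 ± 0.961 against 3.74 ± 0.246, SD, n = 3 arrays each), KRT13 55.6-fold and PLAT 55.4-fold (32.5-fold without FG hypoxia replicate 1). HS3ST1, a heparan sulfate sulfotransferase, was higher by 5.23 ± 0.205 (adjusted p = 2e-07), NTRK2 by 5.22 ± 0.254, the calprotectin subunit S100A8 by 4.88 ± 0.410, IL1R1 by 4.86 ± 0.353 and ceruloplasmin (CP) by 4.75 ± 0.719 (3.94 without FG hypoxia replicate 1 and 5.51 without replicate 3). FG had higher MAGEA6 (-7.31 ± 0.163), TCIM (-7.13 ± 0.621, and -7.81 without L3.6pl hypoxia replicate 3), carbonic anhydrase 2, CA2 (-6.88 ± 0.436), and the glycoprotein hormone subunit CGA (-6.18 ± 0.395). CPS1, OLR1, MAGEA12 and TAGLN were at -6.15 ± 0.268, -6.12 ± 0.181, -5.86 ± 0.222 and -5.78 ± 0.646. Differences in the 2 oxygen states went together, with a Pearson's r across genes of 0.816 and a Spearman's rho of 0.644. Of 3890 genes called in either state 95.1% had the same sign, 791 were higher in both against 102 for independent calls, 744 were lower in both against 73.6, and 1 was called in opposite directions.

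**Figure D4:**
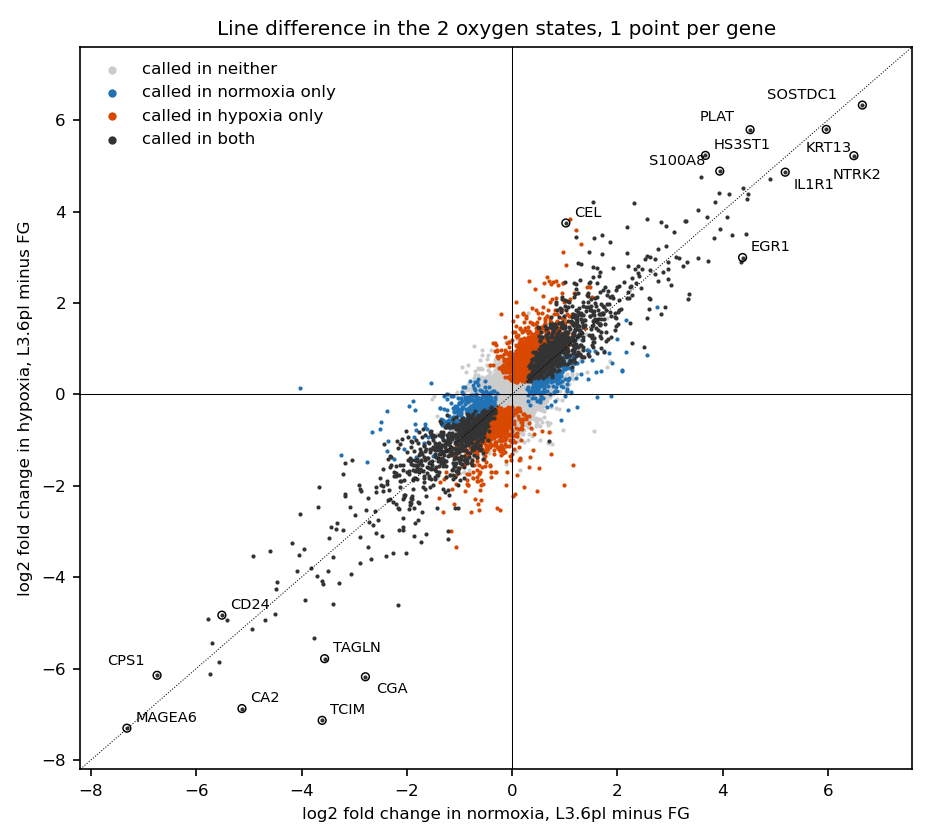
Log2 difference of each gene (points) between L3.6pl and FG in normoxia (x axis) and in hypoxia (y axis), coloured by the oxygen states in which it was called, with the dotted line marking equal differences; XIST and Y-linked genes are left out. SOSTDC1, NTRK2 and KRT13 are far higher in L3.6pl and MAGEA6 and CPS1 far lower in both states, while TCIM and CGA lie below the dotted line.

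Growth factor receptors and ligands were again higher in L3.6pl, with 8 of 15 members higher, also 8 when adjusted over the list alone (mean 1.02, adjusted p = 0.000782; adjusted p = 0.779 with an estimated correlation), including EREG at 2.32 ± 0.279, IGFBP6 at 2.16 ± 0.266, TGFA at 1.93 ± 0.2 and ERBB3 at 1.01 ± 0.151. EGFR was at 1.66 ± 0.401, not called without any of 4 single arrays (adjusted p from 0.0535 to 0.0648). Basal-like genes had 9 of 19 higher and 2 lower, 12 when adjusted over the list alone (mean 0.774, adjusted p = 0.0221; adjusted p = 0.779 with an estimated correlation), with the keratin KRT15 at 2.44 ± 0.346 and TNS4 at 1.73 ± 0.208. That call ended without FG hypoxia replicate 1 (adjusted p = 0.052). Adhesion genes had 8 of 18 higher and 1 lower, 11 when adjusted over the list alone (mean 0.586, adjusted p = 0.0223; adjusted p = 0.779 with an estimated correlation), with the integrins ITGA2 at 2.07 ± 0.231, ITGA6 at 1.88 ± 0.185 and ITGA5 at 1.72 ± 0.159 higher and L1CAM lower at -2.27 ± 0.279. The filter on dim genes ended this call (0.0924). Sterol synthesis was lower in 3 of 14 cases, 6 when adjusted over the list alone (mean -0.930, adjusted p = 0.000579; adjusted p = 0.779 with an estimated correlation), with SC5D at -1.71 ± 0.332.

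The other lists did not pass in hypoxia, although many members did. Matrix genes had 3 of 16 higher and 6 lower, 9 when adjusted over the list alone (mean -0.611, adjusted p = 0.180), with TGFBI at -4.09 ± 0.388, FN1 at -3.05 ± 0.310 and TNC at -2.58 ± 0.231, and were called without FG hypoxia replicate 1 (0.048) or L3.6pl hypoxia replicate 2 (0.0458). Angiogenic factors and cytokines had 8 of 19 higher and 5 lower, 14 when adjusted over the list alone (mean 0.340, adjusted p = 0.363), with VEGFC at 3.25 ± 0.243, CXCL3 at 2.84 ± 0.293 and EDN1 at -4.61 ± 0.461. FGF2 was lower at -0.74 ± 0.131 (adjusted p = 0.00303). Proteases had 7 of 18 higher and 3 lower, 13 when adjusted over the list alone (mean 0.478, adjusted p = 0.363), with PLAU at 2.50 ± 0.278, TIMP1 at 1.65 ± 0.153 and MMP7 at -2.47 ± 0.344. MMP9 was at -0.43 ± 0.166 (adjusted p = 0.109, and 0.0156 with the block or 0.0286 without L3.6pl hypoxia replicate 3). Mesenchymal markers had 6 of 19 higher and 5 lower (mean -0.334, adjusted p = 0.932), with TGFB1 at 2.10 ± 0.211. Interferon-stimulated genes had 5 of 18 higher and 2 lower, 11 when adjusted over the list alone (mean 0.286, adjusted p = 0.188), with OAS1 at 1.68 ± 0.146. NRF2 targets had 4 of 21 higher and 5 lower (mean -0.215, adjusted p = 0.385), with ALDH1A3 at 3.42 ± 0.225 and ALDH1A1 at -4.12 ± 0.449. Immediate early genes had 4 of 12 higher and 4 lower, with a mean of -0.0155 and a median of 0.456 (adjusted p = 0.932), ATF3 being lower at -2.53 ± 0.143. Oxygen sensing had 4 of 10 higher (mean 0.476, adjusted p = 0.188, and called at 0.557 without the 3 arrays that stand apart, 0.0283, but 0.449 with an estimated correlation), with EGLN3 at 2.06 ± 0.278 and EPAS1 at 1.76 ± 0.384, and hypoxia targets 4 of 30 (mean 0.149, adjusted p = 0.691). Glycolysis had 4 of 21 higher (mean 0.165, adjusted p = 0.130) and was called without FG hypoxia replicate 2 (0.0406) or L3.6pl hypoxia replicate 3 (0.0159). Epithelial genes had 1 of 21 higher and 4 lower (mean -0.136, adjusted p = 0.322), the classical subtype 2 of 18 higher and 1 lower (mean 0.331, adjusted p = 0.932), with CEACAM6 at 3.28 ± 0.404, and p53 targets 2 of 16 higher and 1 lower (mean 0.115, adjusted p = 0.526). The bile salt lipase CEL, at 3.75 ± 0.270, was the 1 acinar and endocrine gene of 11 that was higher (mean 0.415, adjusted p = 0.459). Stromal and blood markers had 2 of 11 higher and 2 lower (mean -0.144, adjusted p = 0.526), with LAPTM5 at 2.46 ± 0.333 and COL3A1 at -4.93 ± 0.384. Proliferation had 1 of 26 lower (mean -0.199, adjusted p = 0.363; -0.00694 without FG hypoxia replicate 1 to -0.337 without replicate 2, and called at -0.320 without the 3 arrays that stand apart, 0.0442, but 0.945 with an estimated correlation), stress response 1 of 20 higher and 2 lower (mean -0.205, adjusted p = 0.526), mitochondrial respiration 1 of 19 higher and 1 lower (mean 0.00637, adjusted p = 0.932), heat shock 1 of 8 higher (mean -0.168, adjusted p = 0.898) and DNA repair 0 of 8 (mean 0.0354, adjusted p = 0.932). In all, 3310 genes were called, 1982 higher and 1328 lower in L3.6pl, of which 756 and 586 differed at least 2-fold. Values did not overlap in 3281 of them, nor in 32.1% of all genes where chance gives 10%. The count was 5935 with the block and 2142 without FG hypoxia replicate 2.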

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

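The tests of RNA quality, of an array not from low oxygen and of handling at harvest, the pairing of the lines within each oxygen state and the reassignments of whole pairs were chosen after the results were seen. Of the 5 genes whose hypoxia effect differed between the lines, ATF3 had an interaction of -2.30 and rose in FG, with 0.18 in L3.6pl. CREB5 behaved like it, at -2.25. MAOA was at 2.22 and rose in L3.6pl. SERTAD4 was at 2.01, having fallen in FG from a level that L3.6pl did not reach in either state. RAB31 was at 1.10 and rose in L3.6pl. Same-numbered arrays of the lines pair within each oxygen state, and reassignments that keep these pairs whole number 10, too few for a share under 0.05. Only 1, the real one, gave as many as 5 calls, with a highest other of 0. Of 100 reassignments that ignore the pairs, 1 gave 1003 calls, which points to a structure of the samples. It put the deviations of normoxia replicate 1 of both lines in 1 group, and whether that made the calls was not tested.

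With same-numbered arrays of the lines paired within each oxygen state, 703 genes had a different hypoxia effect, and 271 when the normoxia pair 1 and 1239 when the hypoxia pair 3 was left out. That fit has 10 splits of the pair differences, too few for a share under 0.05, and the highest other split gave 0 calls against 1 real split with 703.

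At the preset correlation of camera, 6 gene lists had a hypoxia effect that differed between the lines. With an estimated correlation each had an adjusted p = 0.761, and 0 lists passed without the 3 arrays that stand apart. With fry 0 lists passed. Immediate early genes were at -0.733, a smaller effect in L3.6pl. Heat shock genes were at -0.582, and at -0.462 without the 3 arrays (adjusted p = 0.00311). Proliferation genes were at -0.675, at -0.043 without FG normoxia replicate 1 (adjusted p = 0.657) and at -0.442 without the 3 arrays (0.000765). The paired fit without normoxia pair 1 gave -0.321 from overlapping differences (0.149 in hypoxia pair 3, 0.0372 in normoxia pair 3). Mitochondrial respiration genes were at -0.226 and interferon-stimulated genes at -0.315. Adhesion genes were at 0.397, a larger effect in L3.6pl. The calls of respiration, interferon and adhesion genes also ended without FG normoxia replicate 1 (0.0954, 0.0632 and 0.117). Of the 10 reassignments of whole pairs, too few for a share under 0.05, 4 gave as many lists as the real 6, with a highest other of 6.

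Normoxia replicate 1 stood apart in both lines in the same direction, with lower proliferation genes, higher sterol synthesis and stress genes and lower NRF2 targets (7.88 against 8.57 in FG, 7.76 against 8.67 in L3.6pl). These arrays and L3.6pl hypoxia replicate 3 had an 18S ribosomal probe value of 10.8, 11.0 and 11.3, against at most 8.90 in the other 9 arrays. If RNA quality moved the same genes the same way in every such array, the deviation of L3.6pl hypoxia replicate 3 should resemble theirs. It correlated with theirs across genes at -0.279. With only 1 other marked array, and that one in hypoxia, RNA quality cannot be told apart from the rest and stays a candidate. A batch shared by same-numbered arrays remains a candidate explanation, since the difference of normoxia arrays 2 and 3 in FG, which the pattern itself does not enter, correlated with that in L3.6pl at 0.476. No biological explanation was tested, because the labels put these arrays in no group of their own.

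HSPA6 and DNAJB1 rose in 5 of the 6 hypoxia arrays and stayed at normoxia levels in L3.6pl hypoxia replicate 3, with DNAJB1 at 8.60 against 11.5 and 11.7 in replicates 1 and 2. Of 240 genes more than 1 log2 unit above normoxia in replicates 1 and 2, 27 kept less than 0.2 of their rise in replicate 3, while the median share was 0.708. An array not from low oxygen is argued against by 28 of the 30 hypoxia targets, which lay above all 3 L3.6pl normoxia values in that array. RNA quality cannot be told apart from the rest. In the other arrays with high ribosomal probes the lower of the 2 median deviations of these genes was 0.0859. Those are normoxia arrays, where these genes lay at least 1.63 log2 units (median) under their risen level, so a missing rise could not show. Handling of the cultures at harvest may also account for it and cannot be told apart from a true difference between cultures: HSPA6 lay more than 1 log2 unit above the highest normoxia value of its line in 5 arrays, which either would give.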

How the results depend on the processing

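Blocks within oxygen states, fits without the arrays that stand apart and estimated correlations with arrays left out were chosen after the data were seen. Of 583 named gene values 323 were called, and 214 of these kept their direction and call under every setting and every left-out array. Of 120 list tests 51 were called, 0 of them under every setting and 34 under all settings other than the estimated correlation and fry. The only called reversal was TNFRSF10B in FG hypoxia, at -0.07 and not called, which became 0.69 (adjusted p = 0.0374) with the mean of all its probe sets, 2 of its 4 probe sets having a positive sign. Counts are given for FG hypoxia, L3.6pl hypoxia, the line difference in normoxia, that in hypoxia, and the interaction, where the setting moved them by more than 1.5 times. Testing all probe sets gave 4699, 2454, 3487, 5705 and 26 calls and an overlap of 1444, with more features tested. Array quality weights gave 5729, 5192 and 6623 in the first 3 and 421 in the interaction. By construction, a log2 fold change of at least 1 lowered the first 4 to 850, 537, 884 and 1342, and an adjusted p below 0.01 lowered all to 860, 475, 1025, 1718 and 2. The replicate block over all arrays gave 2130 calls in L3.6pl hypoxia, 13 in the interaction and an overlap of 1245, and it ended the FG calls of DNA repair and heat shock (adjusted p = 0.065 and 0.064) and the L3.6pl call of oxygen sensing (0.0644). In the hypoxia comparisons the numbers do not pair the arrays, with correlations of -0.217, -0.129 and 0.259 in FG and -0.04, -0.0373 and 0.413 in L3.6pl, where only replicate 3 matched its own number best. The block within each oxygen state gave 4576, 5935 and 703 in the line comparisons and the interaction (271 and 1239 with the normoxia pair 1 or the hypoxia pair 3 left out) and changed no call of the printed results other than those given beside them; the random block gave 4174, 5722 and 366. Without the 3 arrays that stand apart the counts were 3871 and 4179 in the hypoxia comparisons, 19 in the interaction and 2471 in the overlap, and 7 lists passed in the line comparison in hypoxia. The interaction had 12 calls after cyclic loess, 10 with the filter on dim genes, 13 with the mean of probe sets and 10 with trend and robust moderation. Fitting only the 6 arrays compared gave 797 calls in L3.6pl hypoxia, with fewer residual degrees of freedom. With an estimated correlation 5, 2, 0, 0 and 0 lists passed against 13, 18, 10, 4 and 6, with it and FG normoxia replicate 1 or the 3 arrays left out 0, 0, 0, 0 and 0, where fewer arrays are left to test, and with fry 8 in FG hypoxia, 7 in the line comparison in hypoxia and 0 in the interaction. Leaving out each array in turn gave 1029 to 2899, 508 to 2436, 1254 to 2626, 2142 to 3813 and 2 to 23 calls, an overlap of 337 to 1537, a correlation of effects of 0.626 to 0.748, and 10 to 17, 16 to 18, 9 to 12, 4 to 5 and 4 to 8 lists. A single left-out array ended 24 of 74 named gene calls in FG hypoxia, 36 of 77 in L3.6pl hypoxia, 20 of 77 and 16 of 90 in the line comparisons and 3 of 5 in the interaction. Where no construction is named, the cause was not tested. Values near the lowest log2 intensity of 1.96 carry little signal over background, so a low level in one group makes a fold change imprecise.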

Other observations

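The further gene lists, SMAD and YAP targets included, and the same split in both lines were chosen after the results were seen. List p values here were adjusted over these lists alone. Histone demethylases of the JmjC family, which use oxygen as a substrate, rose in hypoxia in both lines, in 6 of 16 cases each (mean 0.561 in FG, adjusted p = 5.43e-05, and 0.621 in L3.6pl, adjusted p = 3.37e-06; adjusted p = 0.376 and 0.373 with an estimated correlation). KDM3A, which is also in the list of hypoxia targets tested above, was higher by 2.05 ± 0.293 in FG and 1.89 ± 0.293 in L3.6pl. Ribosome biogenesis genes fell in 3 of 21 cases in each line (mean -0.504, adjusted p = 0.000151, and -0.523, adjusted p = 1.47e-05; adjusted p = 0.376 and 0.373 with an estimated correlation). Nucleotide synthesis genes fell in 3 of 17 cases in FG and 4 in L3.6pl (mean -0.475, adjusted p = 0.00902, and -0.550, adjusted p = 0.00119; adjusted p = 0.376 and 0.373 with an estimated correlation). Transfer RNA synthetases had 2 of 15 lower in FG (mean -0.349, adjusted p = 0.0193; adjusted p = 0.376 with an estimated correlation) and 1 in L3.6pl (mean -0.211, adjusted p = 0.0837). Autophagy and lysosome genes did not pass, with 3 of 15 higher in FG (mean 0.110, adjusted p = 0.315) and 2 in L3.6pl (mean 0.175, adjusted p = 0.0749).

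Antigen presentation genes set the lines apart in both oxygen states. MHC class II genes were higher in L3.6pl in 7 of 11 cases in normoxia (mean 1.33, adjusted p = 1.47e-05) and 6 in hypoxia (mean 1.29, adjusted p = 0.000185), with adjusted p = 0.254 and 0.234 with an estimated correlation. HLA-DRA was higher by 4.38 ± 0.288 in normoxia and 4.52 in hypoxia, and the invariant chain CD74 by 3.53 ± 0.358 and 2.98. Cancer-testis genes had 1 of 16 higher and 4 lower in normoxia (mean -1.05, median 0.00406, adjusted p = 0.0186, lost at 0.0842 with the block within oxygen state) and 2 higher and 4 lower in hypoxia (mean -1.07, adjusted p = 0.00196), with adjusted p = 0.423 and 0.234 with an estimated correlation.

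Differences between the lines clustered along chromosomes. Over 13300 genes in chromosome order, the line difference correlated with that of the gene 10 places away at 0.139 (permutation p = 1e-04, the smallest that 10000 permutations can give), as copy-number differences between the lines would have it, and copy number was not measured. At that distance the hypoxia effect correlated at 0.00915 (permutation p = 0.141), which argues against genes regulated or hybridising together there. Closer genes (0.0896 for the next gene) and domains regulated in 1 line only stay open. From CREBZF to BIRC2, a window of 41 genes had a median of -0.976 with 38 genes lower in L3.6pl, and from SPICE1 to SLC49A4 one had 0.660 with 38 higher. Medians of windows ran from -0.976 to 0.711, against -0.316 to 0.377 in 100 permutations.

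A weaker SMAD or YAP response in L3.6pl was a hypothesis raised by the smaller effects of CCN1 and ID3 there. In 19 targets whose values had not been looked at, the mean interaction was -0.213 (camera, adjusted p = 0.156 and unadjusted p = 0.0195). With the block these p values were 0.410 and 0.0513. The adjusted p passed in neither fit, which leaves the hypothesis undecided. The same list rose in FG hypoxia in 6 cases and fell in 1 (mean 0.476, adjusted p = 0.00522; adjusted p = 0.331 with an estimated correlation), with 4 and 1 in L3.6pl (mean 0.262, adjusted p = 0.0749). In L3.6pl against FG it had 2 higher and 6 lower in hypoxia (mean -0.635, adjusted p = 0.000228; adjusted p = 0.108 with an estimated correlation) and 2 higher and 5 lower in normoxia (mean -0.422, adjusted p = 0.0186; adjusted p = 0.254 with an estimated correlation).

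Splits of the 6 arrays of a comparison into other groups of 3 number 10, too few for a share under 0.05. The real and the highest other count of genes were 2117 and 1 in FG hypoxia, 1357 and 1 in L3.6pl hypoxia, 2116 and 0 in the line comparison in normoxia, and 3310 and 0 in hypoxia. For the lists the real and highest other counts were 13 and 12, 18 and 16, 10 and 10 (2 splits with as many), and 4 and 8 (7 splits with as many). With the same split in both lines, which keeps the pairs of same-numbered arrays, the 10 splits are again too few. An overlap of hypoxia calls as large as 757 came up in 1, the real one, with a highest other of 0, which follows from the few calls of the other splits in each line and says nothing more about the lines. An absolute correlation as large as 0.705 came up in 2. The other, at 0.745, exchanges normoxia replicate 1 with hypoxia replicate 3 in both lines, and 3 of these 4 arrays stand apart.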
